A study of Mus musculus with 9 samples.

How the data were processed

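Total RNA of nasal mucosa was isolated with a column kit, amplified and biotin-labelled with whole-transcript kits and hybridised to Affymetrix Mouse Gene 1.0 ST arrays, 1 array per sample, per the labels' protocols. The deposited values are log2 expression per probe set, made by the authors with RMA (background correction, quantile normalization and median-polish summary over the arrays), per the submitters' processing notes. The RMA software, its version, the summarization level and the probe set library are not given in the sources used here, and that the scale is log2 was taken from the values, which range from 1.63 to 13.8. The table has 35556 rows and 9 columns, of which 242 rows repeat an earlier row exactly. No detection calls come with it, so signal over background is unknown and low values are reported as they stand.

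Probe sets were named from the platform annotation of 2016. Of the 35556 rows, 23410 had at least 1 gene symbol and were tested. Of these, 21789 had exactly 1 gene, 1621 had several and are not named here, and 12146 rows had none and entered only an alternative. Current symbols and chromosomes came from a RefSeq gene table of assembly GRCm38.p6, which matched 21698 single-gene probe sets by Entrez number; no coordinates were taken from it. The single-gene probe sets represent 19938 genes, 999 of them with over 1 probe set. A gene was represented by its probe set with the highest mean over the 9 arrays.

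The groups were taken from the labels: control, OVA and 4 weeks after the last challenge, 3 arrays each. All 9 arrays entered 1 fit of limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings, 6 residual and 2.98 prior degrees of freedom) with 1 mean per group. The contrasts were OVA minus control, 4-week minus OVA and 4-week minus control. Tests were two-sided, with Benjamini-Hochberg adjustment within each contrast over 23410 probe sets and a threshold of 0.05. A moderated F test asked for any difference among the groups. A probe set moved back if it passed in OVA minus control and in 4-week minus OVA with opposite signs, and persisted if it passed in both contrasts against control with the same sign. Because these contrasts share arrays, groups without effects were simulated 20 times with the observed variances to give the correlation of the changes expected from sharing alone.

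Gene lists for the tissue and treatment were fixed, along with the groups, tests, alternatives and the rule for named genes, before the data were examined. There were 38 lists, of which 37 were tested and 1, of sex-linked genes, served as a check of the labels. They covered type 2 cytokines, responses to IL-4 and IL-13, interferon, acute inflammation, innate receptors, lipid mediators and histamine, immediate early, heat shock, circadian, glucocorticoid, proliferation, remodelling and ion and mucus genes. They also covered markers of eosinophils, mast cells and basophils, neutrophils, T cells, B and plasma cells, antigen-presenting cells, macrophages, mature and immature olfactory neurons, sustentacular, gland, ciliated, respiratory, chemosensory, squamous, muscle, bone, erythroid, glial and fat cells, and 4 gene families (olfactory and vomeronasal receptors, ribosomal proteins and immunoglobulins). Lists were tested with limma's camera at its preset correlation of 0.01, on 1 probe set per gene, with Benjamini-Hochberg adjustment over the 37 lists. Camera with an estimated correlation and fry were alternatives.

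The named genes were, for each contrast, up to 12 higher and up to 12 lower single-gene probe sets with the largest log2 change among those with an adjusted p under 0.05. Predicted transcripts, small RNAs, receptor families and pseudogenes were left out. To these were added a fixed set of allergy and cell type markers and up to 4 members of each list with the smallest p. Genes named as moved back or persisting, the olfactory receptor examples and the small nucleolar RNA family were chosen after their values were seen.

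The fit was tested on simulated data with 23410 probe sets and 50 changed at each fold size. For OVA minus control it recovered 52% of 1.5-fold, 86% of 2-fold, 98% of 3-fold and 96% of 4-fold changes, with 6 false calls among 172. For 4-week minus OVA it recovered 72%, 90%, 100% and 94%, with 6 false calls among 184. For 4-week minus control it recovered 70%, 86%, 96% and 96%, with 10 false calls among 184. Camera, tested for OVA minus control over 19938 genes, passed the 1 raised list and 0 of 36 others, with limma's preset correlation. The simulated genes varied independently, while list members varied together in the data, with an estimated correlation of 0.791 for mature olfactory neuron markers. This run therefore could not show how often camera passes unchanged lists of correlated genes.

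The alternatives were quantile normalization and median centring of the deposited values, the upper 60% of probe sets by mean, every row of the table, 1 probe set per gene, a fit of the compared groups only, eBayes with trend and robust settings, array weights, the replicate number as a block, an unmoderated statistic, an unadjusted p under 0.05 with at least a 1.5-fold change, and leaving out each array in turn. Leaving out X- and Y-linked probe sets was added after seeing the data. No array was left out of the reported values.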

Results

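The series measured gene expression in the nasal mucosa of male-labelled BALB/c mice, an inbred strain often used for allergic airway models, with 9 Affymetrix Mouse Gene 1.0 ST arrays. It followed an allergic rhinitis model in 3 groups of 3 arrays. The control mice received saline throughout. The OVA mice were sensitised to and challenged with ovalbumin, a hen egg protein used as allergen, and were taken 2 hours after the last challenge. The third group, called the 4-week group here, had the same treatment and was taken 4 weeks after the last challenge, a period without allergen. The series title names allergen avoidance, so the comparisons ask what the challenge changed, which of those changes were gone after the allergen-free period, and which were not. The array medians lay between 6.38 and 6.45 on the log2 scale. Arrays of the same group correlated across genes at r = 0.986 to 0.992, and arrays of different groups at r = 0.973 to 0.988. The number of arrays, 3 per group, limits the precision of every value below. The labels do not say that each array came from a separate animal, so the p-values measure only the spread between these samples, which may be technical. The fit was repeated 9 times, each without another array, and the text says in how many of these 9 fits the call of a named gene was lost. In the order of the comparisons below, 22 of 55, 26 of 63 and 46 of 81 calls of genes named in the text were lost in 0 of them.

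The sex-linked transcripts of the 3 arrays labelled control did not match their label. Xist, the RNA that silences an X chromosome in female cells, had a mean of 10.81 ± 0.26 (SD, n = 3) on the log2 scale in the arrays labelled control, against 4.29 ± 0.07 in the OVA arrays and 4.33 ± 0.08 in the 4-week arrays. This is a difference of 90.5-fold from the other 6 arrays. The Y-linked genes went the other way. Eif2s3y was 31.0-fold, Uty 16.7-fold and Kdm5d 5.02-fold lower in the arrays labelled control than in the other 6. All 3 arrays labelled control carried the female pattern and all 6 other arrays the male pattern, although every sample is labelled male. The arrays labelled control therefore differ from both other groups in sex-linked expression as well as in treatment, and a difference from the arrays labelled control cannot by itself be assigned to one of these. Only the comparison of the 4-week group with the OVA group has the same sex pattern on both sides. Of these groups, only the OVA mice were taken shortly after a challenge and its handling. Every sample carries the same labelled age range, so age at collection cannot be compared. Age, handling and time of day at collection were not tested. Their effects cannot be told apart from those of the allergen-free period.

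**Figure D1:**
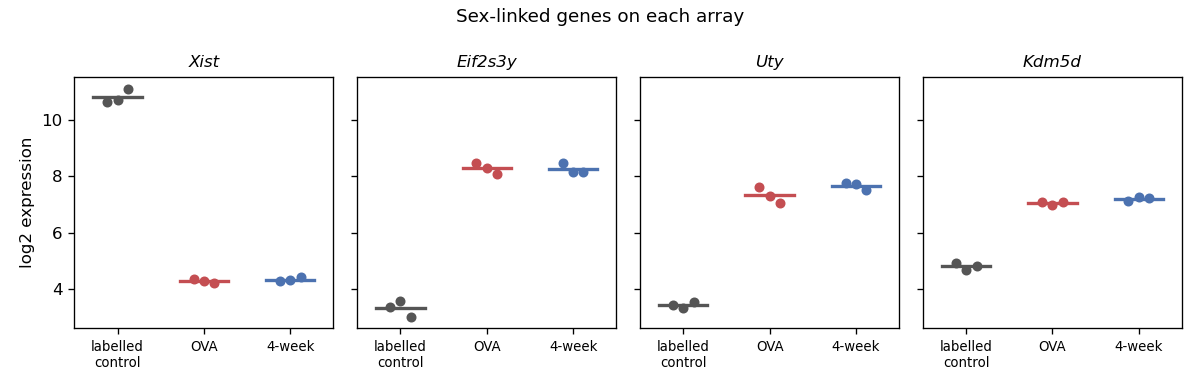
Log2 expression of Xist, Eif2s3y, Uty and Kdm5d on each array (points), with the group mean (horizontal line), in the arrays labelled control, the OVA group and the 4-week group, 3 arrays each. The 3 arrays labelled control are above 10.6 for Xist, where no other array exceeds 4.42, and are lowest for all 3 Y-linked genes.

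The OVA arrays, taken 2 hours after the last challenge, held more transcript of several inflammatory cytokines and their signalling partners than the arrays labelled control. Il1b, a cytokine of early inflammation, was 4.57-fold higher (log2 change 2.19, SE 0.24, n = 3 per group, adjusted p = 0.00764). Osmr, the oncostatin M receptor, was 2.99-fold higher (adjusted p = 0.00171) and Bcl3, a regulator of NF-kappaB, 2.93-fold higher (adjusted p = 0.016). Il1a was 2.56-fold, Timp1, a metalloproteinase inhibitor, 2.35-fold and Tnfaip3, an NF-kappaB inhibitor, 2.13-fold higher. Among the lower genes were several of plasma proteins made mainly by the liver: Hpx (hemopexin) was 3.69-fold, Rbp4 (retinol-binding protein) 3.35-fold, Ttr (transthyretin) 2.45-fold and Alb (albumin) 2.19-fold lower. Il1b, Osmr, Hpx, Rbp4 and Ttr passed whichever of the 9 arrays was left out, while the call of Tnfaip3 was lost in 8 of the 9 fits (adjusted p up to 0.152), that of Timp1 in 4 and those of Bcl3, Il1a and Alb in 2 each. All of these directions are taken against arrays labelled control that carry the female pattern.

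Of 23410 probe sets, 305 differed between OVA and the arrays labelled control at an adjusted p under 0.05 in limma, 183 higher and 122 lower. Apart from the sex-linked genes, and among the genes named by rule, the largest rises besides those above included H2-M10.3, a non-classical MHC gene (log2 change 2.30, SE 0.34), B4galnt2, a glycosyltransferase (1.86, SE 0.33), Nhlh1, a transcription factor of newly formed neurons (1.66, SE 0.19), Lilr4b, a leukocyte receptor (1.47, SE 0.16), and Steap4, a metalloreductase induced in inflammation (1.41, SE 0.24). After Xist, the largest fall was that of Bpifb9a, a secreted protein of nasal glands, whose log2 change was −4.80 (SE 0.88, adjusted p = 0.0415). Bpifb9a varied widely between arrays, from 9.87 to 12.10 in the arrays labelled control and from 5.12 to 8.21 in the OVA arrays, and its change was −5.45 without control replicate 1, −5.71 without OVA replicate 3 and −4.16 without OVA replicate 1, where it did not pass (adjusted p = 0.133). Cps1 (−1.56), Cyp4a14 (−1.51), Slc38a4 (−1.14), Ifi27l2a (−1.13), Fgg (−1.11) and Itih3 (−1.09) also fell. Calls were lost in 7 of 9 fits for B4galnt2 (adjusted p up to 0.125), in 6 for Bpifb9a, 5 for Steap4 and Ifi27l2a and 3 for H2-M10.3, Fgg and Itih3. The number was 1 for Cps1 and 0 for Nhlh1, Lilr4b, Cyp4a14 and Slc38a4.

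The fixed list of acute inflammatory genes had the lowest p in camera at the preset correlation, but not with an estimated correlation (unadjusted p = 0.0501). It and the immediate early list did not pass fry (adjusted p = 0.0846 and 0.0555). The acute inflammatory list had a median log2 change of 1.09 over 25 measured members. Il1a, Il1b and Tnfaip3 rose and none fell, and 16 rose when adjusted over the list alone (camera adjusted p = 1.73e-12; adjusted p = 0.334 with an estimated correlation). Of 23 immediate early genes, 5 rose and none fell, among them Ier3 (1.22), Nr4a3 (1.12) and Klf6 (0.64); 14 rose when adjusted over the list alone (median 0.50, camera adjusted p = 7.26e-12; adjusted p = 0.276 with an estimated correlation). Markers of immature olfactory neurons had 5 of 16 members higher, with Sox11 at 1.22 (SE 0.10, adjusted p = 0.00171), Stmn1 at 1.05 (SE 0.10, adjusted p = 0.00302) and Dpysl3 at 0.73; 7 rose when adjusted over the list alone (median 0.27, camera adjusted p = 8.15e-09; adjusted p = 0.276 with an estimated correlation; fry adjusted p = 0.0463). Olfactory receptor genes shifted down, with 48 of 1027 lower and 1 higher, or 169 lower and 18 higher when adjusted over the list alone. Their median was −0.19 (camera adjusted p = 4.74e-09; adjusted p = 0.528 with an estimated correlation), and Olfr39 fell by 1.62 and Olfr1295 by 1.55 on the log2 scale. The calls of Nr4a3, Ier3 and Klf6 were lost in 8, 6 and 2 of the 9 fits without an array, and those of Sox11, Stmn1, Dpysl3, Olfr39 and Olfr1295 in 0.

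Genes known to respond to IL-4 or IL-13, the cytokines of allergic inflammation, had a median change of 0.48 over 28 members (camera adjusted p = 1.06e-05; adjusted p = 0.334 with an estimated correlation). Only Cish, a cytokine signalling inhibitor, rose within this list over all genes (0.98, adjusted p = 0.026, lost in 4 of the 9 fits without an array); adjusted over the list alone 4 rose and 1 fell. The best known allergy markers had large changes that did not pass, with wide differences between arrays of a group. Mcpt1, a mucosal mast cell protease, had a log2 change of 4.12 (SE 0.88, adjusted p = 0.0659), with 9.37, 5.98 and 9.95 on OVA replicates 1, 2 and 3 against a mean of 4.31 in the arrays labelled control. Retnla, an alternatively activated macrophage product, stood at 6.99, 3.88 and 7.79 on the same arrays against 3.60 (log2 change 2.62, adjusted p = 0.164). Chil4, a chitinase-like protein, changed by 2.68 (adjusted p = 0.304) and Muc5ac, the main secreted airway mucin, by 1.69 (adjusted p = 0.336). For both, the arrays labelled control were split (Chil4 at 8.79, 9.10 and 5.18, Muc5ac at 9.72, 8.28 and 6.19), and without control replicate 3 the changes were 1.42 and 0.76. Without OVA replicate 2, Mcpt1 (5.35, adjusted p = 0.00257) and Retnla (3.79, adjusted p = 0.00454) passed. Clca1, a goblet cell product, had 0.96 (adjusted p = 0.0914, and 0.0498 without 4-week replicate 1), and the eosinophil chemokines Ccl11 and Ccl24 had 0.90 and 0.82 (adjusted p = 0.205 and 0.256). The type 2 cytokines themselves were near the arrays labelled control: Il4 at 0.08, Il5 at −0.02 and Il13 at 0.30, with adjusted p between 0.337 and 0.941. Il33, an epithelial alarmin, had −0.85 (adjusted p = 0.0818), the eosinophil granule genes Epx and Prg2 had 0.15 and 0.20, the ciliated cell factor Foxj1 had −0.02 and the mature olfactory neuron marker Omp had −0.44 (adjusted p = 0.208). Values within 0.30 of 0 were also found for Cd4 (0.22), Foxp3 (−0.04), Ccl17 (−0.08) and Fcer1a (0.11), none of which passed. Chil3, Alox15, Muc5b and Cpa3 did not pass either, and Cpa3, a mast cell carboxypeptidase, had 1.08 (adjusted p = 0.194); without OVA replicate 2, Cpa3 (adjusted p = 0.0319), Muc5b (0.0373) and Il33 (0.0375) passed as well.

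**Figure D2:**
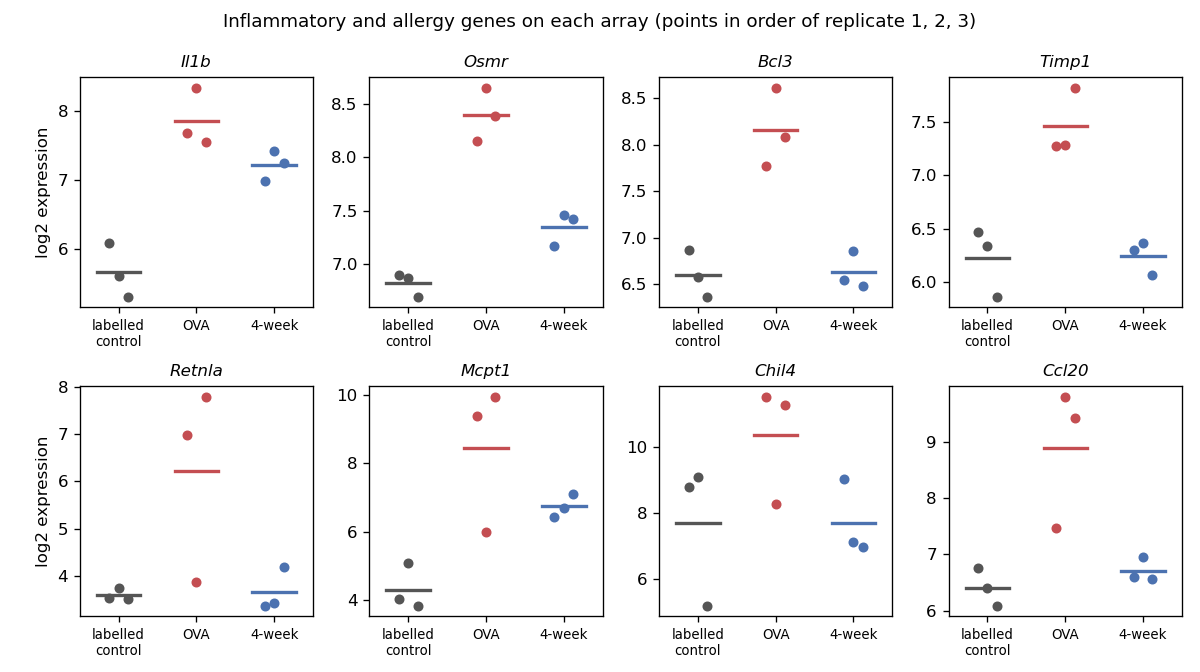
Log2 expression of 8 inflammatory and allergy genes on each array (points), with the group mean (horizontal line), in the arrays labelled control, the OVA group and the 4-week group, 3 arrays each. Il1b, Osmr, Bcl3 and Timp1 are higher on every OVA array than on every array labelled control, while Retnla, Mcpt1 and Chil4 are lower on OVA replicate 2 than on the other two OVA arrays.

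In all, 17 of 37 lists passed camera in this comparison, 14 up and 3 down. The others that passed upward were markers of mast cells and basophils (median 0.42), macrophages (0.46) and antigen-presenting cells (0.16), immunoglobulin genes (0.65), glucocorticoid-responsive genes (0.32), Toll-like receptor and innate genes (0.17), heat shock genes (0.17), lipid mediator and histamine genes (0.16), respiratory epithelium markers (0.24) and ion and mucus transport genes (0.17). Ciliated cell markers (−0.18) and ribosomal protein genes (−0.07) passed downward. Their adjusted p lay between 0.276 and 0.75 with an estimated correlation. Of the 15 mast cell and basophil markers, none passed over all genes, but adjusted over the list alone 8 rose and 3 fell. The 20 lists that did not pass had adjusted p from 0.0681 to 0.987 and covered type 2 cytokines, eosinophils, neutrophils, T cells, B and plasma cells, interferon, circadian, proliferation and remodelling genes, mature olfactory neurons, sustentacular, gland, chemosensory, squamous, muscle, bone, erythroid, glial and fat markers and vomeronasal receptors. The neutrophil list had a negative median (−0.22) and mean (−0.06) but an upward test, and the gland list a positive median (0.07) and a negative mean (−0.28). The mean of the squamous list was positive (0.03), with a median of −0.03, as was that of the remodelling list (0.04, median −0.02). The chemosensory list had a median of −0.03 and a mean of −0.00243 with an upward test.

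At an unadjusted p under 0.05 the comparison gave 3834 probe sets, and 5030 (21.5%) had no overlap between the groups, where chance gives 10%. The count of 305 fell to 63 without control replicate 2, 87 without OVA replicate 1, 110 without OVA replicate 3, 141 without control replicate 3, 192 without control replicate 1 and 197 without OVA replicate 2. The share of higher genes, 60%, lay between 47.7% (the compared groups only) and 70% (dim filter) under the alternatives that left out no single array. With the correlation estimated, camera passed 0 lists (4 at an unadjusted p under 0.05) and fry 1, and another division of the same 6 arrays gave 21 lists with the preset correlation. The antigen-presenting cell and lipid mediator lists did not pass without control replicate 3 or OVA replicate 3 (adjusted p from 0.114 to 0.258), nor did the ciliated and ribosomal lists without control replicate 1 or OVA replicate 3 (0.154 to 0.592). Other lists passed when an array was left out (adjusted p from 0.00137 to 0.049): interferon, proliferation and mature olfactory neurons without control replicate 1, and remodelling without control replicate 2. So did eosinophils, mature olfactory neurons and erythroid genes without OVA replicate 2, mature olfactory neurons without 4-week replicate 1 or 2 and after quantile scaling (0.0411) or median centring (0.0492), and vomeronasal receptors, upward and with a median of 0.04, without OVA replicate 1.

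At 4 weeks after the last challenge, a pair of chemokines and several inflammatory regulators were lower than in the OVA arrays. Ccl20, a chemokine for dendritic cells and lymphocytes, was 4.55-fold lower than in the OVA group (log2 change −2.19, SE 0.51, n = 3 per group, adjusted p = 0.0397) and Cxcl2, a neutrophil chemokine, 4.39-fold lower (adjusted p = 0.0344), while the chemokine Ccl9 had 0.08 (adjusted p = 0.854). Ccl20 was 7.48-fold lower without OVA replicate 1, and Cxcl2 2.75-fold lower without OVA replicate 2. Tnip3 was 3.24-fold, Bcl3 2.88-fold, Sbno2 2.43-fold and Socs3, a cytokine signalling inhibitor, 2.18-fold lower; a second probe set of Socs3 had −0.17 (adjusted p = 0.563). Among the higher genes, the cytochrome P450 gene Cyp4a12a was 2.71-fold, Cyp2b10, another of that family, 2.47-fold and Aox3, an aldehyde oxidase, 2.00-fold higher. Tsc22d3, a glucocorticoid-induced leucine zipper protein, was 2.10-fold higher (log2 change 1.07, SE 0.11, adjusted p = 0.00314). With each of the 9 arrays left out in turn, Ccl20 did not pass in 8 cases (adjusted p up to 0.138), Cxcl2 (up to 0.0884) and Cyp2b10 in 6, Socs3 in 5 and Aox3 in 2. Bcl3, Tnip3, Sbno2, Cyp4a12a and Tsc22d3 passed in all 9.

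The comparison called 1481 of 23410 probe sets, 893 higher and 588 lower at 4 weeks. The largest fall of a probe set with a single gene was that of Sprr1a, a cornified envelope protein also induced by injury (−2.72, SE 0.65, adjusted p = 0.0422). Ksr2 (−1.61), Nr1d1, a repressor in the circadian clock (−1.26), Rasgrp4 (−1.24), Pcdh10 (−1.22), Timp1 (−1.21) and Sting1 (−1.15) fell as well. Further rises were those of Fads2b (1.23), Ccn1, a matrix protein (1.13), Cyp4a12b (1.09), Ccdc180 (1.05), Sp140 (1.01), Calb1 (1.01), Rgs22 (0.99) and Gpx8 (0.98). Ccdc180 was measured by 27 probe sets, of which 13 rose and none fell. Without 1 array, the calls of Rgs22 were lost in 8 of 9 fits (adjusted p up to 0.121), those of Sprr1a (up to 0.139), Cyp4a12b, Sp140 and Calb1 in 7, of Fads2b and Rasgrp4 in 6 and of Ksr2, Pcdh10 and Ccn1 in 2. Those of Nr1d1, Timp1, Sting1, Ccdc180 and Gpx8 were kept in all 9.

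Ribosomal protein genes formed the most clearly raised group, with 14 of 55 higher and none lower and a median of 0.23; adjusted over the list alone 28 rose and 1 fell (camera adjusted p = 6.01e-16; adjusted p = 0.551 with an estimated correlation; fry adjusted p = 0.00954). Rpl10a rose by 0.73 (SE 0.08), Rpl27a by 0.72, Rpl4 by 0.67 and Rpl24 by 0.65, and these 4 passed whichever array was left out. Of the 25 acute inflammatory genes, Ccl20, Cxcl2 and Socs3 fell and none rose, or 9 fell when adjusted over the list alone (median −0.55, camera adjusted p = 1.87e-05; adjusted p = 0.774 with an estimated correlation). Il1b did not pass here (−0.64, adjusted p = 0.153). Genes responding to IL-4 or IL-13 had a median of −0.30, with Cish, whose call was lost in 5 of 9 fits without an array, the only 1 of 28 that fell, also when adjusted over the list alone (camera adjusted p = 0.0061; adjusted p = 0.774 with an estimated correlation). Retnla had −2.55 (adjusted p = 0.1), Chil4 −2.66 (0.21), Mcpt1 −1.69 (0.278), Muc5ac −1.48 (0.297) and Ccl11 −1.06 (0.0813), none of which passed. Without OVA replicate 2, Retnla (adjusted p = 0.00806), Mcpt1 (0.0165), Ccl11 (0.0271), Chil3 (0.0412) and Alox15 (0.0439) did, and without 4-week replicate 1 Clca1 did (−0.95, adjusted p = 0.0466). Il4, Il5 and Il13 had −0.17, −0.14 and −0.44 (adjusted p from 0.101 to 0.483), and Il13 passed without OVA replicate 1 (0.0323).

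Ciliated cell markers had a median of 0.26 and 1 of 24 members higher, also adjusted over the list alone: Dnah9, a dynein heavy chain of motile cilia (0.91, SE 0.21), while Foxj1 had 0.05 (camera adjusted p = 3.72e-05). The ciliated marker Spef2 was measured by 22 probe sets, of which 5 rose and none fell, but the probe set that represented it in the list did not pass. Sustentacular cell markers had Gstm1 (0.48) and Gsta4 (0.35) higher among 16, or 4 higher adjusted over the list alone, with a median of 0.21 (camera adjusted p = 0.00115). Of 11 heat shock genes, Hspa1a (0.42) and Dnaja1 (0.38, with −0.13 and adjusted p = 0.437 at its second probe set) rose, or 5 adjusted over the list alone (median 0.17, camera adjusted p = 0.0103). Eosinophil markers had a median of −0.32, and only Cebpe (−0.54) fell among 9, also adjusted over the list alone (camera adjusted p = 0.0289). The call of Cebpe was lost in each of the 9 fits without an array (adjusted p from 0.0509 to 0.1), that of Gstm1 in 8, those of Gsta4 and Dnah9 in 7 and those of Hspa1a and Dnaja1 in 4. Each of these 4 lists had adjusted p = 0.774 with an estimated correlation. So did the olfactory receptors, with a median of −0.10, 31 of 1027 lower and 1 higher, or 9 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0165), and the vomeronasal receptors, with a median of −0.10 and 0 of 169 passing in limma (camera adjusted p = 0.0289). After quantile scaling neither receptor family passed, and the medians were −0.02 for olfactory and 0.00153 for vomeronasal receptors, so the sign of the vomeronasal median turned. The eosinophil (adjusted p = 0.0582), heat shock (0.0958) and sustentacular lists (0.0958) did not pass after quantile scaling either.

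The 28 lists that did not pass had adjusted p between 0.0767 and 0.889. Glucocorticoid-responsive genes went both ways, with Tsc22d3, Ddit4 (0.71) and Sgk1 (0.70) higher and the metallothionein Mt2 (−0.57) lower among 13. The circadian list, with 16 members, had Nr1d1, Bhlhe40 (−1.10) and Dbp (−0.53) lower and Arntl, which encodes the clock activator BMAL1, higher (0.63). Time of day at collection was not tested and may differ between the groups, so these shifts are not assigned to the allergen-free period. Of the immediate early genes, Nr4a3 (−1.02), Gadd45b (−0.92) and Junb (−0.52) fell while Ccn1 rose. Of these genes the calls of Arntl, Gadd45b and Junb were lost in 7 of 9 fits without an array, of Dbp in 6, Nr4a3 in 5, Mt2 in 4 and Ddit4 in 2, and of Sgk1 and Bhlhe40 in 0. The chemosensory list had Gnat3, a taste transduction G protein subunit, higher (0.55, adjusted p = 0.00436, kept in all 9 fits), with a median of −0.02, a mean of −0.01 and an upward test. Bone markers had a median of −0.00811 and a mean of −0.01 with an upward test. Proliferation genes had a median of −0.00584 and a mean of 0.0079. The ion and mucus list had a median of −0.02 and a mean of 0.02 with a downward test. The medians of these 4 lists and of the type 2 cytokine list (−0.06) turned positive after quantile scaling and after median centring, and that of the gland list turned negative and that of the glucocorticoid list went from 0.01 to −0.02 after quantile scaling. Median centring brought the macrophage, mast cell and basophil, neutrophil and squamous lists past the threshold downward (adjusted p from 0.0125 to 0.0483), and quantile scaling the immature olfactory neuron list (0.0138).

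At an unadjusted p under 0.05 there were 5598 probe sets, and 6580 (28.1%) had no overlap between the groups, where chance gives 10%. The call count was 446 without OVA replicate 3, 467 without 4-week replicate 2, 572 without OVA replicate 2, 819 without 4-week replicate 1, 850 without 4-week replicate 3 and 949 without control replicate 2. The share of higher genes, 60.3%, was 50.2% with 1 probe set per gene, 51.2% over every row and 78.1% after median centring. With the correlation estimated, camera passed 0 of 37 lists (1 at an unadjusted p under 0.05) and fry 1, against 9 with the preset correlation, where another division of the same 6 arrays gave 17. The eosinophil list did not pass without OVA replicate 1, OVA replicate 3 or 4-week replicate 2 (adjusted p from 0.0675 to 0.139). The same held for the vomeronasal list without OVA replicate 2, OVA replicate 3, 4-week replicate 1 or 4-week replicate 2 (0.163 to 0.62) and the olfactory receptors without OVA replicate 2 (0.0974) or 4-week replicate 2 (0.826, with an upward test). Other lists passed when an array was left out (adjusted p from 7.2e-06 to 0.0407): erythroid and immunoglobulin genes without OVA replicate 1, mast cells and basophils and macrophages without OVA replicate 2, and immediate early and immature neuron genes without OVA replicate 3. So did neutrophils, glucocorticoid, mature and immature neuron and immunoglobulin genes without 4-week replicate 1, and erythroid and remodelling genes without 4-week replicate 3.

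The 4-week arrays differed from the arrays labelled control in interleukin 1 genes that were also higher in the OVA arrays, and in some antibody genes. Il1b was 2.93-fold higher (log2 change 1.55, SE 0.24, n = 3 per group, adjusted p = 0.00624) and Il1a 2.10-fold higher. Jchain, which joins polymeric antibodies in plasma cells, was 4.95-fold higher (2.31, SE 0.41, adjusted p = 0.00919), and the antibody light chain genes Igkv4-55, Igkv8-30 and Igkv5-43 were 3.73-, 2.71- and 2.52-fold higher, with Igkv4-55 at 2.33-fold without 4-week replicate 1. With each of the 9 arrays left out in turn, Il1b, Il1a, Jchain, Nr1d1 and the liver genes below passed in every case, and Igkv4-55, Igkv8-30 and Igkv5-43 did not in 4, 3 and 2. The B and plasma cell list, with 1 of 14 members higher, did not pass (median 0.06, camera adjusted p = 0.284). Nr1d1 was 3.84-fold lower (−1.94, SE 0.13, adjusted p = 0.000556). Hpx, Cps1, Rbp4 and Alb were again 2.44- to 3.85-fold lower than in the arrays labelled control, which carry the female pattern here as above.

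This comparison called 3364 of 23410 probe sets, 1855 higher and 1509 lower. Besides those genes and the sex-linked ones, and among the genes named by rule, Mrps21, a mitochondrial ribosomal protein (1.69), H2-M10.3 (1.54), B4galnt2 (1.51), the chemokine Ccl9 (1.48) and Mgat4a (1.46) rose most. After Xist, and outside the olfactory receptors, the largest falls included those of Pnliprp1, a lipase-related protein (−2.02, SE 0.58, adjusted p = 0.0478), which ranged from 4.87 to 7.79 in the arrays labelled control and had −2.73 without control replicate 1 and −1.27 without control replicate 3 (adjusted p = 0.0561), Cyp4a14 (−1.68), Fgg (−1.44), Usp17ld (−1.43), the granule protease Prtn3 (−1.41), Fabp1 (−1.40) and myeloperoxidase, Mpo (−1.37). Without 1 array, the call of Pnliprp1 was lost in 8 of 9 fits (adjusted p up to 0.125), of Mpo in 5, Usp17ld in 4, H2-M10.3 in 3, B4galnt2 in 2 and Fabp1 in 1. Mrps21, Ccl9, Mgat4a, Cyp4a14, Fgg and Prtn3 passed in all 9. Allergy markers whose changes after OVA did not pass did not pass here either: Retnla at 0.07, Chil4 at 0.02, Muc5ac at 0.21, Clca1 at 0.26, Ccl11 at −0.16 and Ccl24 at −0.04, with adjusted p between 0.46 and 0.994. The values of Chil4 and Muc5ac rest on control replicate 3, without which they were −1.24 and −0.73. Mcpt1 had 2.43 (SE 0.88, adjusted p = 0.0938, and 0.00832 without OVA replicate 2). Il4, Il5, Il13 and Il33 had −0.09, −0.16, −0.14 and −0.51, with adjusted p from 0.115 to 0.651.

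Glucocorticoid-responsive genes were higher in the 4-week arrays than in the arrays labelled control, with 6 of 13 higher and none lower. This list had also passed upward in OVA minus the arrays labelled control (median 0.32). From OVA to 4 weeks it did not pass (median 0.01, camera adjusted p = 0.122). Tsc22d3 rose by 1.28 (SE 0.11, adjusted p = 0.00107), Sgk1 by 0.94, Ddit4 by 0.61 and Fkbp5 by 0.58, and adjusted over the list alone 8 rose and 1 fell (median 0.52, camera adjusted p = 3.16e-05; adjusted p = 0.422 with an estimated correlation; fry adjusted p = 0.0132). Of 11 heat shock genes 5 rose, among them Hsph1 (0.66) and Dnaja1 (0.64, and 0.18 without passing at its second probe set), and 7 when adjusted over the list alone (median 0.34, camera adjusted p = 1.33e-05; adjusted p = 0.422 with an estimated correlation; fry adjusted p = 0.0132). Immediate early genes had 6 of 23 higher, with Ccn1 at 0.94, Klf6 at 0.78 and Jun at 0.69, or 8 adjusted over the list alone (median 0.28, camera adjusted p = 0.000114; adjusted p = 0.688 with an estimated correlation). Immunoglobulin genes had 3 of 11 higher, the kappa genes named above, or 5 adjusted over the list alone (median 1.12, camera adjusted p = 0.000455; adjusted p = 0.469 with an estimated correlation). Among ribosomal protein genes 15 of 55 rose and 2 fell, one being Rps19 (−0.93), or 18 and 3 adjusted over the list alone (median 0.16, camera adjusted p = 1.79e-07; adjusted p = 0.469 with an estimated correlation; fry adjusted p = 0.0296). The calls of Ddit4, Fkbp5 and Ccn1 were lost in 1 of the 9 fits without an array, and those of Tsc22d3, Sgk1, Hsph1, Dnaja1, Klf6, Jun and Rps19 in 0.

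Olfactory receptor genes were lower in the 4-week arrays, with 206 of 1027 lower and 3 higher, or 281 and 5 adjusted over the list alone (median −0.32, camera adjusted p = 4.65e-12; adjusted p = 0.688 with an estimated correlation). Olfr39 fell by 1.54, Olfr1295 by 1.41 and Olfr24 by 0.78 on the log2 scale, and the median was −0.23 after quantile scaling. Markers of mature olfactory neurons had Kirrel3 (−0.68), Rtp1, a receptor transport protein (−0.63), and Gnal, the olfactory G protein subunit (−0.44), lower and the calcium-binding S100a5 higher (0.35) among 17, or 4 lower and 1 higher adjusted over the list alone. The call of S100a5 was lost in each of the 9 fits without an array (adjusted p from 0.0503 to 0.119), that of Gnal in 7, Rtp1 in 4 and Kirrel3 in 3. The 3 olfactory receptors named passed in all 9. The mature neuron list had a median of −0.27 and did not pass (camera adjusted p = 0.111), but it passed after quantile scaling (0.00173) and median centring (0.0482). Omp had −0.48 (adjusted p = 0.0669, and 0.0277 without 4-week replicate 1). Of 16 markers of immature olfactory neurons 6 were higher, among them Sox11 (1.08, SE 0.10, adjusted p = 0.00136), Stmn1 (0.89) and Dpysl3 (0.69), all kept in the 9 fits, while 12 of the 16 had negative values in 4-week minus OVA (median −0.14); adjusted over the list alone 6 rose and 1 fell (median 0.19, camera adjusted p = 0.00385; adjusted p = 0.688 with an estimated correlation).

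Further lists that passed upward, of 12 in all, were sustentacular (median 0.26), respiratory epithelium (0.14), ion and mucus (0.26) and erythroid genes (0.38), and the vomeronasal receptors passed downward (−0.12, 4 of 169 lower, and 0 adjusted over the list alone). Their adjusted p lay between 0.469 and 0.909 with an estimated correlation, and the sustentacular, respiratory, ion and mucus and vomeronasal lists did not pass after quantile scaling (0.0973 to 0.769), nor the respiratory list after median centring (0.0611). The other 25 lists had adjusted p from 0.0518 to 0.953, the acute inflammatory and ciliated lists lying nearest to the threshold (both 0.0518). Within them, the circadian genes Dbp (−1.03) and Nr1d1 fell and Arntl (0.66), Nfil3 (0.69) and Per2 (0.46) rose. As above, time of day at collection was not tested for these genes. Without 1 array, Nfil3 did not pass in 8 of 9 fits (adjusted p up to 0.145), Per2 in 6 and Arntl in 3. Dbp and Nr1d1 passed in all 9. The circadian list had a median of −0.07 with an upward test, the IL-4 and IL-13 list a median of −0.03 with a mean of 0.03, the gland list a median of 0.04 with a mean of −0.25, the fat list a median of −0.18 with a mean of 0.00424, and the chemosensory list a median of −0.04 and a mean of −0.01 with an upward test. The IL-4 and IL-13, chemosensory and muscle medians turned positive after either scaling, that of the type 2 cytokine list after quantile scaling, and the circadian and glial medians after median centring. In the neutrophil list Mpo and Elane (−1.14) fell while Il1b rose, and its median was −0.32 (camera adjusted p = 0.568). Mpo and Elane each lost their call in 5 of 9 fits.

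At an unadjusted p under 0.05 there were 7696 probe sets, and 8194 (35.0%) had no overlap between the groups, where chance gives 10%. The call count was 1560 without 4-week replicate 2, 1803 without control replicate 2 and 1988 without control replicate 3. The share of higher genes, 55.1%, was 49.4% with 1 probe set per gene, 52.6% over every row, 75.7% after median centring and 78.2% with the unmoderated statistic. With the correlation estimated, camera passed 0 of 37 lists (3 at an unadjusted p under 0.05) and fry 3, and another division of the same 6 arrays gave 19 with the preset correlation. The erythroid list did not pass without control replicate 1, 4-week replicate 1 or 4-week replicate 2 (0.0527 to 0.086), nor did the vomeronasal list without control replicate 3, 4-week replicate 1 or 4-week replicate 2 (0.134 to 0.524). Nor did the respiratory list pass without control replicate 3 or 4-week replicate 3 (0.128 to 0.328), the sustentacular list without 4-week replicate 1 (0.0582), nor the ion and mucus list without 4-week replicate 2 (0.0506). Other lists passed when an array was left out (adjusted p from 0.0015 to 0.0385): interferon, innate, acute inflammatory, ciliated and mature olfactory neuron lists without control replicate 1, and remodelling without control replicate 2 or 4-week replicate 3. The acute inflammatory and ciliated lists also passed without OVA replicate 1, the first also without OVA replicate 2 or 4-week replicate 1 and the second without OVA replicate 3 or 4-week replicate 2. Mature neurons passed without 4-week replicate 1 and proliferation without 4-week replicate 3.

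**Figure D3:**
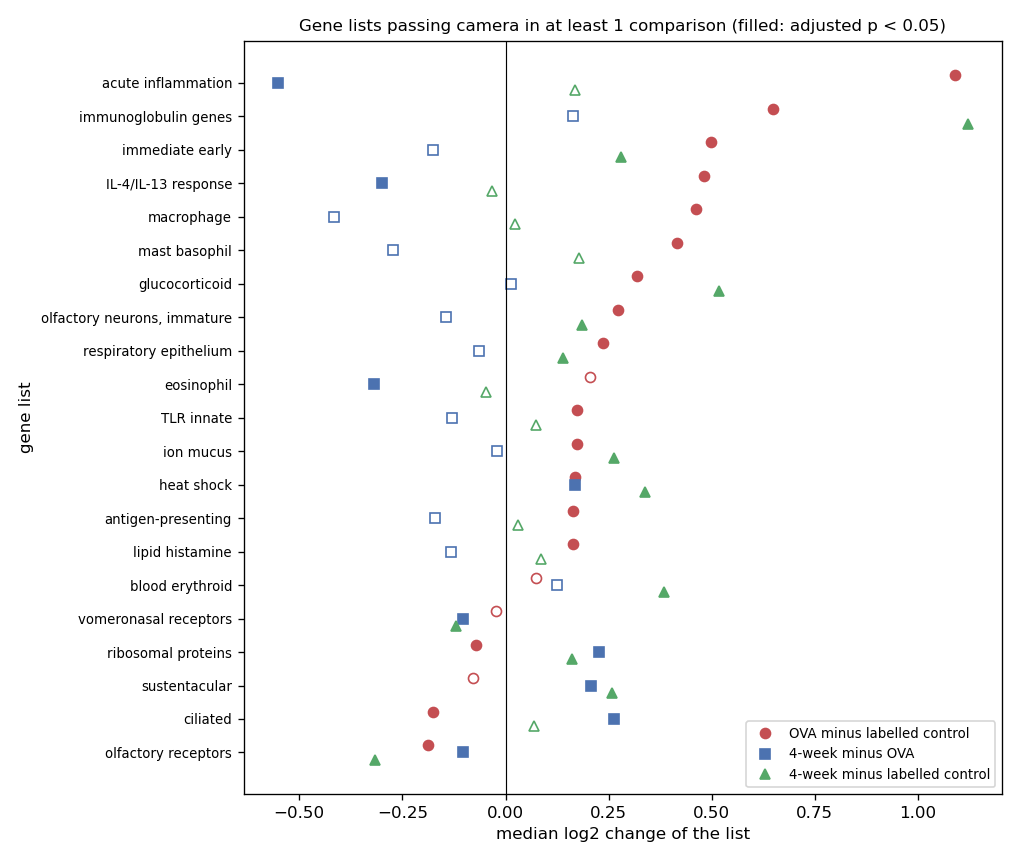
Median log2 change of each gene list that passed camera in at least 1 comparison, for OVA minus the arrays labelled control, 4-week minus OVA and 4-week minus the arrays labelled control (filled symbols, adjusted p under 0.05; open symbols, not passing). The acute inflammatory list lies at 1.09 after OVA and −0.55 from OVA to 4 weeks, and the ribosomal list at −0.07 and 0.23, while the vomeronasal, glucocorticoid and ion and mucus medians of 4-week minus OVA turn sign after quantile scaling, as does that of IL-4 and IL-13 responses for 4-week minus the arrays labelled control, and the eosinophil median of the last comparison and the ion and mucus median turn after median centring.

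Of the 305 probe sets that differed between OVA and the arrays labelled control, 74 moved back, that is, they also differed between the 4-week and OVA groups in the opposite direction. OVA was higher in 64 of these and lower in 10, and 68 of the 74 did not pass between the 4-week arrays and the arrays labelled control. Besides Bcl3, Tnip3, Sbno2, Timp1 and Sting1, they included Csf2rb, the shared receptor chain of IL-3, IL-5 and GM-CSF (1.22 after OVA and −0.87 from OVA to 4 weeks), Csf3r, the neutrophil growth factor receptor (1.03 and −1.02), Cish (0.98 and −0.82), Stat3 (0.45 and −0.32) and Il1rn, the IL-1 receptor antagonist (0.60 and −0.53). Acot2, Ephx1 and Rpl38 moved back from lower values. Only 12 of the 74 moved back in each of the 9 fits without an array, among them Osmr, and 12 in none of them, among them Stat3, Il1rn and Rpl38. This call was lost in 8 of the 9 for Csf2rb, Csf3r and Ephx1, 7 for Cish and Acot2, 5 for Sting1, 4 for Timp1, 3 for Tnip3, 2 for Bcl3 and 1 for Sbno2. A total of 192 probe sets, 93 higher and 99 lower, still differed from the arrays labelled control in the same direction at 4 weeks, and 45 did neither. A difference of the arrays labelled control alone, such as that in sex pattern, would also count as persisting, and the 192 include Xist, Eif2s3y, Uty and Kdm5d and the liver genes Hpx, Rbp4, Ttr, Cps1, Alb and Fgg. Osmr and Lilr4b did both: Osmr went from 1.58 after OVA to 0.53 at 4 weeks, and Lilr4b from 1.47 to 0.65. Without 1 array, the persisting call was lost in 5 of 9 fits for Osmr (adjusted p at 4 weeks up to 0.101) and in 4 for Lilr4b (up to 0.0787), as was the moved back call of Lilr4b in 4. Of the 192, 28 persisted in all 9 fits and 16 in none. The sex-linked genes, Hpx, Rbp4 and Ttr were kept in all, Cps1 was lost in 1, Alb in 2 and Fgg in 3. Also kept in all were the higher genes Il1b, Sox11, Stmn1, Dpysl3 and Nhlh1 and the lower genes Cyp4a14, Slc38a4, Olfr39 and Olfr1295. Il1a was lost in 2, Jun in 7 and Fkbp5 and Nr1d1 in 8. For these genes too, treatment and the sex pattern of the arrays labelled control cannot be told apart. The OVA arrays enter both contrasts of the moved back count, and the arrays labelled control both contrasts of the persisting count. Independent lists would share 9.25 and 22.4, and part of the excess may come from the shared arrays. Another part comes from genes with several probe sets, such as Snord118 and Rpl38. With 1 probe set per gene, 65 moved back and 176 persisted. Over all genes, the changes of the OVA and 4-week groups against the arrays labelled control correlated at r = 0.614, against 0.502 in 20 simulations without effects, and their covariance was 0.0527 against 0.0118, a difference of 0.0409. The changes from control to OVA and from OVA to 4 weeks correlated at r = −0.306, weaker than the −0.503 of the simulations, with a covariance of −0.0218 against −0.0118. Genes are not independent replicates. The F test over the 3 groups called 2910 of 23410 probe sets, but 1195 without 4-week replicate 2, 1468 without control replicate 2, 1915 without 4-week replicate 1 and 1919 without control replicate 3. The moved back count was 20 without OVA replicate 3, 22 and 37 without control replicates 2 and 3, 43 without OVA replicate 1, and 46, 31 and 42 without 4-week replicates 1, 2 and 3. The persisting count was 40 and 96 without control replicates 2 and 3, 46, 108 and 74 without OVA replicates 1, 2 and 3, and 118 without 4-week replicate 2.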

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

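The tests of hepatocyte RNA, of both explanations for the olfactory receptors, the choice of the liver genes and the restriction to opposite signs below were chosen only after the results were seen.

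All 3 arrays labelled control carried Xist and lacked Y-linked transcripts, although every sample is labelled male. An exchange of labels between groups would not by itself give this pattern, since no sample of the series is labelled female. Female mice or a wrong sex label may explain the pattern, and 4 genes that escape X inactivation were tested: their median was 0.18 higher in the arrays labelled control than in the other 6 (Kdm6a 0.33, Eif2s3x 0.23, Kdm5c 0.13 and Ddx3x −0.07, against 0.05 for the other 784 X-linked genes), and 2 of the 4 had every array labelled control above every other array. This median lies between the bounds of 0.2 and 0.1 set for and against female RNA, so the test by itself does not decide. Xist was at 10.62, 10.7 and 11.11 on the arrays labelled control and at most 4.42 on the others. Eif2s3y was at 3.35, 3.579 and 3.004, and at least 8.075 on the others. These values argue against male RNA on the arrays labelled control. How such RNA came under a male label stays open, and a swap with samples outside the series was not tested. Sex and treatment differ together between the arrays labelled control and the rest, and in a comparison with those arrays alone their effects cannot be told apart.

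The 11 liver genes of the pattern, most of them for plasma proteins, had a median 1.21 higher in the arrays labelled control than in the other 6 arrays. Array-wide scaling is argued against as the source of a shift of this size. The medians of the arrays labelled control, 6.41 to 6.44, lay within the 6.38 to 6.45 of the other 6 arrays. RMA normalizes before its probe set summary, and the deposited values still differed in spread, with interquartile ranges from 2.397 to 2.654. After quantile normalization of these values the median of the pattern was still 1.14. RNA from hepatocytes carried into these samples was not settled. The 6 most abundant liver transcripts that were measured had a median difference of 0.31, less than the pattern (Alb 1.21, Apoc1 0.40, Apoa2 0.35, Apoh 0.27, Apoa1 0.12 and Trf −0.00433, with Alb in both sets). This was not under the bound of 0.3 set against the explanation, though the 5 other than Alb had a median of 0.27. The median level of the 6 in the arrays labelled control, 5.78, lay below the 6.43 of all probe sets, a second bound set against it. Neither value expected under the explanation was thus seen. Levels of different probe sets do not measure a transcript's share, so it is not excluded. A difference in sex or in treatment may explain the pattern and stays open, since the design gives both together and neither was tested.

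The 1027 olfactory receptor genes had a median of −0.32 in 4-week minus the arrays labelled control. A wider spread of values that lowers dim probe sets is argued against as the whole of this shift. Of 10000 random gene lists matched on mean expression, 0% had a median as low (lowest −0.11), and the receptor median stayed at −0.23 after quantile normalization. It may give a part, since the matched lists had a median of −0.0851. Random lists also do not carry the shared variation of the receptors. The receptor score was lowest on 4-week replicate 2 (−0.36), against −0.0522 and −0.0762 on replicates 1 and 3 and 0.12 to 0.318 on the arrays labelled control. Fewer mature olfactory neurons may explain the shift: the median of 17 neuron markers was −0.27, and 0% of 10000 matched lists were as low (median 0.11, 5th percentile −0.02). Random lists do not carry the co-regulation of a marker list, the same list did not pass camera (adjusted p = 0.111; 0.00173 after quantile normalization, 0.0482 after median centring, 0.00903 without control replicate 1 and 0.0015 without 4-week replicate 1), its member S100a5 was higher at 4 weeks (adjusted p from 0.0503 to 0.119 without any 1 array, so lost in 9 of 9 fits), and its score on 4-week replicate 1 (0.157) lay above those of control replicates 1 and 2 (−0.0898 and 0.0769). Loss of neurons, lower expression per neuron and the sex pattern of the arrays labelled control stay open.

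For some genes and lists the estimates against the arrays labelled control had opposite signs at the 2 times, and the difference itself, 4-week minus OVA, passed in limma or, for lists, in camera. Both effects share the arrays labelled control. Of 153 genes named in the text, 63 had a difference that passed, 26 of them whichever of the 9 arrays was left out, and 35 of the 63 had opposite signs. Opposite signs do not show opposite changes: 0 of the 35 passed in limma against the arrays labelled control at both times and 13 at neither, and for others, such as Sbno2 (1.27 and −0.02), an estimate lay near 0. The difference was positive for Cyp4a12a (1.44), Cyp2b10 (1.31), Fads2b (1.23), Ccn1 (1.13), Cyp4a12b (1.09), Ccdc180 (1.05), Sp140 (1.01), Calb1 (1.01), Aox3 (1.00), Rgs22 (0.99), Gpx8 (0.98), Dnah9 (0.91), Ephx1 (0.76), Rpl10a (0.73), Rpl27a (0.72), Ddit4 (0.71), Rpl4 (0.67), Rpl38 (0.65), Rpl24 (0.65), S100a5 (0.52), Gstm1 (0.48) and Gsta4 (0.35). It was negative for Sprr1a (−2.72), Snord118 (−2.12), Tnip3 (−1.69), Ksr2 (−1.61), Snora52 (−1.41), Snora16a (−1.34), Sbno2 (−1.28), Rasgrp4 (−1.24), Pcdh10 (−1.22), Sting1 (−1.15), Socs3 (−1.12), Bhlhe40 (−1.10) and Mt2 (−0.57). Among lists, the median of 4-week minus OVA was −0.32 for eosinophil markers, 0.21 for sustentacular cells, 0.26 for ciliated cells and 0.23 for ribosomal protein genes. With an estimated correlation none of these 4 passed (adjusted p = 0.551 for ribosomal protein genes and 0.774 for the others), and the eosinophil and sustentacular lists did not pass after quantile normalization (0.0582 and 0.0958).

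The counts were compared with those of other divisions of the same arrays into groups of the same sizes. With 6 arrays there are 10 divisions, too few for a share under 0.05. For probe sets, 1 of 10 divisions, the labelled one, gave as many as the 305 of OVA against the arrays labelled control (highest other 1), 1 of 10 as many as the 1481 of 4-week against OVA (highest other 21) and 1 of 10 as many as the 3364 of 4-week against the arrays labelled control (highest other 1). For gene lists in camera, 2 of 10 gave as many as 17 (highest other 21), 8 of 10 as many as 9 (highest other 17) and 6 of 10 as many as 12 (highest other 19), in the same order. With all 9 arrays and 100 divisions, 1, the labelled one, gave as many as the 2910 probe sets of the F test (highest other 1024). The same held for the 74 that moved back (highest other 4). Divisions that mix the arrays labelled control with the rest also mix the sex patterns, which adds spread within their groups. Their low counts therefore do not exclude chance.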

How the results depend on the processing

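Every alternative here was fixed before the data were examined except leaving out X- and Y-linked probe sets, which was chosen after seeing the data.

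In the order OVA against the arrays labelled control, 4-week against OVA and 4-week against the arrays labelled control, the counts of 305, 1481 and 3364 probe sets were within 1.5-fold under quantile normalization, median centring, the dim filter, trend and robust settings, array weights, the replicate block and without X and Y, and lay between 213 and 410, 1397 and 1987, and 2727 and 4220. The F test called between 2597 and 3714 under them. No scaling moved the median of all probe sets by over 0.1. Without X- and Y-linked probe sets the counts were 301, 1434 and 3259. Testing every row of the table left 143 in the first comparison and the persisting count at 93 and the moved back count at 39, and 1 probe set per gene left 946 in the second; which probe sets were tested changed, and the cause was not tested further.

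Fitting only the compared groups, with 6 arrays in place of 9, called 109, 737 and 2054. The unmoderated statistic called 8, 1 and 271. An unadjusted p with a 1.5-fold change called 694, 738 and 1150, and 137 moved back and 332 persisted under it. The cause was not tested for these rules.

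Leaving out 1 array gave 63 to 305, 446 to 1361 and 1560 to 2966 probe sets, 1195 to 2249 in the F test, 20 to 65 moved back and 40 to 190 persisting; the group that lost an array had fewer samples. Lists passing camera were 13 to 20, 6 to 13 and 10 to 16. The downward shift of the olfactory receptors from OVA to 4 weeks had medians from −0.155 to −0.019, the last without 4-week replicate 2, where the test turned upward without passing. The vomeronasal receptors in OVA minus the arrays labelled control had medians from −0.0585 to 0.0446, the last without OVA replicate 1, where the test passed upward. The cause was not tested.

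Camera with an estimated correlation passed 0 lists in each comparison (4, 1 and 3 at an unadjusted p under 0.05), where the preset correlation passed 17, 9 and 12. Fry, which does not compare a list with other genes, passed 1, 1 and 3. Quantile normalization passed 5 lists from OVA to 4 weeks, and the dim filter 5 there and 6 between the 4-week arrays and the arrays labelled control; the cause was not tested.

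The labels do not say that arrays with the same number belong together. With the replicate number as a replicate block, 213, 1397 and 3271 probe sets were called, of which 180, 1115 and 2787 were also called without it, 64 moved back, 127 persisted, the F test called 2655, and 17, 10 and 15 lists passed. Of the 9 arrays, 7 correlated best with an array of their own number, which is a hint and no proof of a pairing.

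Among named genes, 64, 72 and 112 results passed. Under the alternatives, 912 of 1261, 1046 of 1427 and 1734 of 2201 values of these still passed, the rest kept their direction without passing, and 0 turned sign in limma. Xist, Kdm5d and Eif2s3y passed under each alternative that tested them in the first comparison, 0 genes did in the second and 17 in the third. Of values for results that did not pass, 66 of 3792, 88 of 3518 and 111 of 2567 passed in the same direction. Among lists that passed, 225 of 272, 109 of 143 and 148 of 191 values did so again.

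No detection calls or background probes came with the values, so signal over background is unknown. A small change of a dim probe set, such as those of Il4, Il5 or many olfactory receptors, was not detectable with these arrays where it did not pass, and is not shown to be absent.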

Other observations

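The families and genes in this part were chosen after their values were seen, apart from the proliferation and interferon lists, and nothing in it was tested beyond limma and the scaling alternatives named.

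Many, though not all, small nucleolar RNAs guide the modification of ribosomal RNA. Of 51 measured, 24 were lower and 1 higher in 4-week minus OVA, with a median of −0.62 (−0.57 after quantile normalization and −0.56 after median centring). In OVA minus the arrays labelled control 7 were higher and 0 lower in limma, with a median of 0.27 (0.25 and 0.29), and in 4-week minus the arrays labelled control 2 were higher and 12 lower, with a median of −0.19 (−0.19 and −0.12). Snora44 had 2.04 after OVA and −1.83 from OVA to 4 weeks (adjusted p = 0.00128 and 0.00174), Snord118 had 1.67 and −2.12, and Snora16a had 1.23 and −1.34. Snora52 was near the arrays labelled control after OVA (0.15, adjusted p = 0.504) and had −1.26 at 4 weeks. The calls of these 4 genes were kept whichever array was left out.

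A few genes of cell division and of the interferon response were higher at 4 weeks than in the arrays labelled control, within lists that did not pass: Mki67 at 0.70 (adjusted p = 0.0404), Nusap1 at 0.44, Top2a at 0.38 (−0.14 without passing at its second probe set), Rsad2 at 0.74 and Irgm1 at 0.74. With each of the 9 arrays left out in turn, Irgm1 did not pass in 8 cases, Mki67, Nusap1 and Top2a in 7 each, and Rsad2 in 4. Of mast cell and basophil genes, Kit was higher (0.56, adjusted p = 0.0411), while Mcpt8 (−0.46) and Mrgprb1 (−0.44) were lower, with calls lost in 6, 4 and 3 of the 9 cases, and Mcpt2 had 3.78 in OVA minus the arrays labelled control (adjusted p = 0.0574). OVA replicate 2, where the mast cell protease Mcpt1 was lowest of the OVA arrays, had the highest score of the acute inflammatory list, 0.984 against 0.16 and 0.47 on OVA replicates 1 and 3.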
